A study of Mus musculus with 2 samples.

How the data were processed

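Single-cell RNA sequencing was performed on 1 sample of adult mouse back skin and 1 sample of adult mouse lung. Per the labels, both tissues were digested with collagenase, an enzyme that frees cells from connective tissue, and cells positive for GFP, CD4, CD3 and CD45 were sorted. GFP marks expression of Foxp3, the transcription factor that defines regulatory T cells (Tregs). The skin came from Foxp3-CreERT2GFP mice and the lung from Foxp3-GFP mice of a strain named Tachilla in the labels, both on the C57Bl/6 background. Libraries were made with 10x Single Cell 3' v2 chemistry, which tags each captured RNA molecule near its 3' end with a unique molecular identifier (UMI).

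The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, and the barcodes had already been called as cells by the authors. Cell Ranger and the mm10 genome are named in the submitters' processing notes without a version. Per the file headers the lung matrices were written by software version 3.0.2, and the header of the skin matrix names none. The skin matrix lists 27998 genes and the lung matrices list 31053, so that the annotations differed. The 27514 gene identifiers in both were compared, of which 1027 carry another symbol in the other list. The symbol of the lung list is used here, as in Rflnb, which the skin list names Fam101b. Gene positions were looked up by identifier in GENCODE release M21 for GRCm38, the assembly also called mm10, for 27403 of these identifiers, and are counted from 1.

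There are 2 lung matrices. All 8626 barcodes of the second occur among the 8730 of the first, its 22309104 UMIs are 92.1% of those that the first holds for the same barcodes, and the totals per barcode correlate across barcodes at r = 0.9998. It was therefore treated as a second, shallower table of the same cells, and the first was used alone.

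Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 1 skin barcode for few genes, and 134 skin and 89 lung barcodes for mitochondrial UMIs. The doublet caller Scrublet, run in scanpy 1.11.5, marked 0.0309% of skin and 0.0231% of lung cells, too few to have worked. The 6% of cells with the highest doublet scores were removed in its place, 388 from skin and 518 from lung, leaving 6079 and 8123 cells. Each library was clustered on 2000 variable genes, 30 principal components and 15 neighbours with leidenalg 0.10.2 at a resolution of 0.8. A cluster received a name when at least 3 markers of a cell type were 2-fold above the other cells, and at least 1 marker (2 for types other than T cells) stood among its 10 leading genes with no other type ahead. Fold values of clusters had 10 CPM added to both sides. Clusters whose best type was not a T cell type, with at least 3 of its markers 4-fold up, were left out of the comparison. These held 138 skin and 312 lung cells. Clusters were rebuilt here, so their names can differ from those used by the study.

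The counts of the remaining 5941 skin and 7811 lung cells were summed per library, 13881591 and 20993520 UMIs in shared genes, and divided by that total to give CPM, counts scaled to the same library total. The ratio of skin over lung was taken as log2 of (CPM + 5), which understates differences of low genes. Among genes with at least 20 CPM in either library, those at least 4-fold apart on this scale were counted. List members counted as at least 2-fold apart or within 2-fold were counted on the same scale. Folds printed for single genes are ratios of CPM without the added 5, so that Top2a, 2.23-fold higher in skin as a plain ratio, counts as within 2-fold. With 1 sample per group no test was possible and none was run. Levels carry exact 95% Poisson intervals, ratios the matching exact binomial intervals, and shares of cells exact Clopper-Pearson intervals, all of which cover counting error only. A count of 0 was read against a limit of 3 counts per library, 0.216 CPM in skin and 0.143 CPM in lung. Shares of cells with a UMI are given raw and after thinning every cell to 1000 UMIs, which left out 0 skin and 80 lung T cells.

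Gene lists, cell type markers, thresholds and the rule for named genes were fixed before the data were examined. That rule takes the 15 genes with the highest and the 15 with the lowest ratio among those with at least 50 CPM in either library. It leaves out T cell receptor and immunoglobulin segments, mitochondrial, ribosomal protein and haemoglobin genes and models named Gm or Rik. It adds the genes of the sort gate, 5 sex-linked genes, up to 4 members with the widest ratio in each list, and the 10 leading genes of each cluster. Other list members printed below were chosen after their values were seen. There were 39 lists, 22 of T cell programmes and 17 of T cell classes and other cell types. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression, and a list was taken to stand apart below percentile 2.5 or above 97.5. The percentile describes these libraries and is not a test.

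On simulated pools drawn at the 2 depths from the lung levels with 200 seeded genes, 0 of 66 genes changed 2-fold passed the 4-fold rule. It was passed by 65 of 77 genes (84.4%) changed 8-fold, by 53 of 54 (98.1%) changed 16-fold, and by 0 of 4307 unchanged genes. The intervals held the true ratio for 95.3% of 4504 genes. A list of 12 genes changed 8-fold reached percentile 100, and 8 of 200 lists of unchanged genes (4%) fell outside 2.5 to 97.5. Each gene was drawn on its own, and ribosomal protein and mitochondrial genes were left unchanged, unlike in the libraries compared. The 4% is therefore not a rate for the lists below.

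The comparison was repeated under 15 alternatives fixed in advance and 6 that were chosen after seeing the data. The first set covers scaling, cell filters, doublets, non-T clusters, cells with a Foxp3 UMI, the lung matrices, the expression floor, the added CPM, equal weight per cell, and totals without mitochondrial and ribosomal protein genes. The second covers cells with a Cd3e UMI, cells low in early response genes, lung cluster 3 alone, and leaving out proliferating clusters, X and Y genes, or genes overlapping an unshared gene or far higher in non-T clusters. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9 were used.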

Results

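The transcriptomes of Foxp3-reporter T cells sorted from adult mouse back skin and lung were compared, 1 library per tissue. The skin library held 6601 cell barcodes and 16190303 UMIs, with a median of 2058 UMIs and 1035 genes per barcode. In lung there were 8730 barcodes and 24293511 UMIs, with a median of 2353.5 UMIs and 903.5 genes. After filtering, 5941 skin cells (median 2026 UMIs) and 7811 lung cells (median 2335 UMIs) in T cell clusters were pooled per tissue. There were no replicates, so the difference between skin and lung has no replicate check. Mouse strain, library, annotation version and, by the sex-linked genes below, the sex of the animals differ together with tissue.

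The question was how Tregs of skin and lung differ in the genes they express. Skin cells were higher in type 2, repair, suppressive and effector Treg genes. Areg, which encodes the EGF receptor ligand amphiregulin, stood at 1285 CPM (1266 to 1304) in skin and 41.5 CPM (38.8 to 44.4) in lung, and Il10, which encodes an anti-inflammatory cytokine, at 324 against 8.43 CPM. Il13, a type 2 cytokine gene, stood at 199 CPM in skin with 0 UMIs in lung. Lung cells were higher in genes of recirculating lymphocytes, such as S1pr1, which encodes the sphingosine 1-phosphate receptor used to leave tissue, at 273 CPM in lung against 25.9 in skin.

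Of 5577 genes with at least 20 CPM in either library, 212 were at least 4-fold higher in skin and 72 at least 4-fold higher in lung, so that 74.6% were on the skin side. The median log2 ratio of all these genes was 0.37. Median-of-ratios scaling brought it to 0.05 with 139 skin and 91 lung genes (60.4% on the skin side), and totals without mitochondrial and ribosomal protein genes brought it to −0.04 with 175 and 136 genes (56.3%). Ribosomal protein genes took 19.3% of UMIs in skin T cells and 39.0% in lung T cells. The skin annotation alone lists ribosomal protein pseudogenes such as Rpl23a-ps3 and Rpl13-ps3, at 639 and 306 CPM in skin T cells. Whether the differing annotations contribute to this gap was not tested.

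Besides Areg, Il10 and Il13, 12 genes made up the skin end of the ranking. Lmna, the gene of the nuclear lamins A and C (ENSMUSG00000028063, chromosome 3, 88480147 to 88509956), was 114-fold (103 to 127) higher in skin at 1924 CPM. Cxcr6, a chemokine receptor gene (ENSMUSG00000048521, chromosome 9, 123806475 to 123811760), was 198-fold (158 to 252) higher at 698 CPM. Calca, which encodes the neuropeptide CGRP (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357), reached 388 against 0.238 CPM, and the ratio of 1627 has a counting interval of 697 to 5014. Ccr10, the receptor gene for the epidermal chemokine CCL27, was 147-fold (94.8 to 241) higher. Il1r2, a decoy receptor gene for interleukin 1, stood at 159 against 1.67 CPM, and Anxa1, Pxdc1 and Gcnt1 at 239, 166 and 124 CPM in skin against 1.29, 0.953 and 0.238 in lung. Il1r2 and Anxa1 were higher still in skin non-T clusters, at 532 and 800 CPM, against 11.6 and 130 CPM in those of lung. Lmna also differed there, at 939 against 145 CPM, so these 3 differences are not particular to T cells. Pxdc1 was not higher in skin there, at 54.4 against 74.9 CPM. AY036118 stood at 1579.6 against 51.8 CPM, with like levels in the non-T clusters (1446 and 49.1 CPM), so its difference is not particular to T cells. Bcl2a1d, at 292 against 8.62 CPM, has near-identical paralogs that can share reads and is uncertain. Tonsl, at 312 against 2.91 CPM, overlaps a gene model that the lung annotation alone lists, so its difference is uncertain as well. Xist, at 1239 CPM in skin and 0 UMIs in lung, is treated with the sex-linked genes.

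The positions of the cytokine genes are ENSMUSG00000029378, chromosome 5, 91139599 to 91148432 for Areg, ENSMUSG00000020383, chromosome 11, 53631324 to 53634702 for Il13 and ENSMUSG00000016529, chromosome 1, 131019845 to 131024974 for Il10. The lung limit of 3 counts puts Il13 at least 1392-fold higher in skin.

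At the lung end, Satb1, the gene of a chromatin organizer (ENSMUSG00000023927, chromosome 17, 51736187 to 51833290), was 14.9-fold (13.5 to 16.6) higher in lung, Ly6c1 15.5-fold (13.6 to 17.8) and S1pr1 (ENSMUSG00000045092, chromosome 3, 115710433 to 115715072) 10.5-fold (9.46 to 11.7). Gimap4 and Gimap7, GTPase genes of lymphocytes, stood at 506 and 152 CPM in lung against 55.6 and 9.29 in skin. Klf3, Tubb2a, Igfbp4, Plcxd2 and Rflnb were between 10.2-fold and 19.9-fold higher in lung. Sftpc (surfactant protein C) and Scgb1a1 (a secretory protein of airway club cells) stood at 193 and 143 CPM in lung T cells with 0 UMIs in skin, at least 893-fold and 662-fold higher. Both were far higher in the non-T clusters of lung, at 73793 and 29442 CPM.

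The sex-linked genes parted the libraries, with the pattern of female cells in skin and male cells in lung. Xist was at least 8672-fold higher in skin. Eif2s3y, Ddx3y, Uty and Kdm5d, all on the Y chromosome, stood at 80.8, 76.0, 17.3 and 10.8 CPM in lung with 0 UMIs in skin, at least 374-fold higher in lung for Eif2s3y and 352-fold for Ddx3y.

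**Figure D1:**
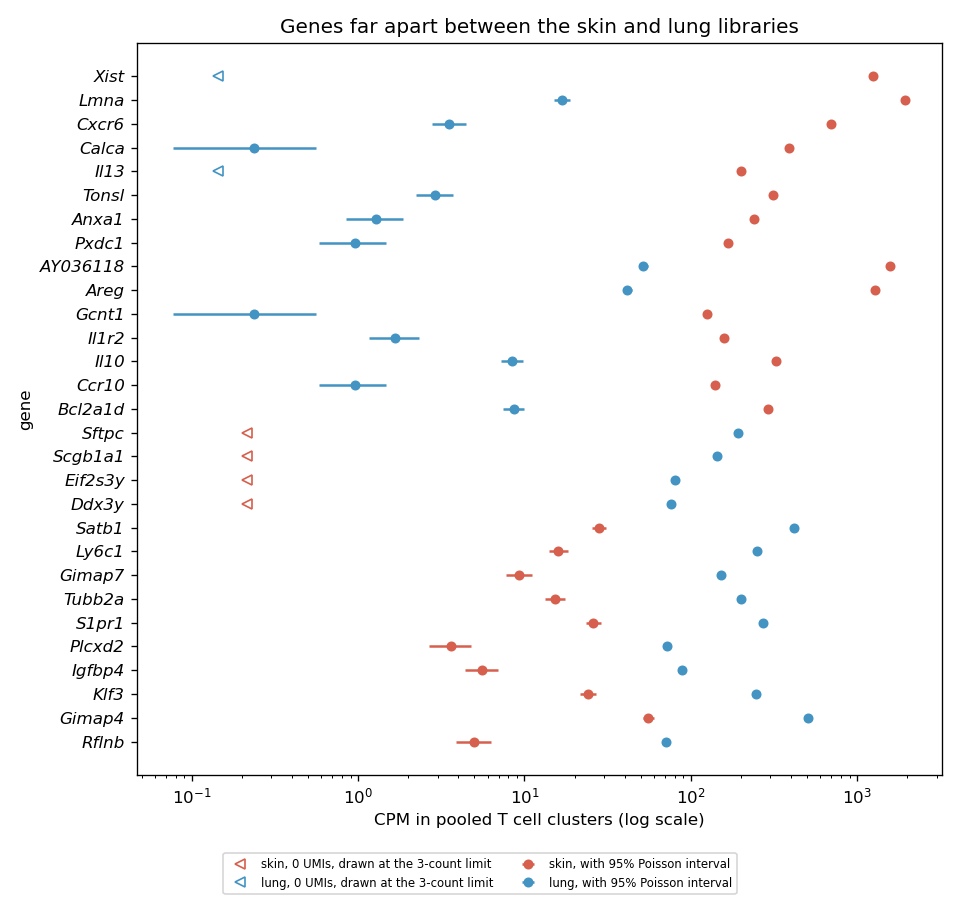
CPM in pooled T cell clusters on a log scale for the 15 genes with the highest and 14 of the 15 with the lowest ratio of skin over lung; points are the skin (red) and lung (blue) libraries with exact 95% Poisson intervals, and open triangles mark 0 UMIs at the 3-count limit. Lmna lies at 1924 CPM in skin and 16.8 in lung, and Satb1 at 28.0 and 419.

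Genes of the sort gate were compared first as a check of the sort. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) was 1.85-fold (1.58 to 2.18) higher in skin, at 24.6 CPM (22.1 to 27.4) against 13.3 CPM (11.8 to 14.9). A Foxp3 UMI was found in 326 of 5941 skin T cells (5.49%, 4.92 to 6.10) and 271 of 7811 lung T cells (3.47%, 3.07 to 3.90). At 1000 UMIs per cell the shares were 2.37% (2.001 to 2.79) and 1.47% (1.22 to 1.77). Non-T clusters had shares of 1.45% of 138 skin cells (0.176 to 5.14; median 4572 UMIs) and 2.24% of 312 lung cells (0.907 to 4.57; median 2461 UMIs), and 0% and 0.373% thinned. Cd4 stood at 170.2 against 110.1 CPM, Cd3g at 1658 against 823 CPM, Ptprc, which encodes CD45, at 816 against 438 CPM and Cd3e at 575 against 736 CPM. Cd3d differed by a log2 ratio of 0.11, and by −0.23 and −0.30 under the median-of-ratios scaling and without mitochondrial and ribosomal protein genes. Under these 2 scalings all 6 genes shifted toward lung. Foxp3 went from a log2 ratio of 0.70 to 0.42 and 0.41, and Cd3g from 1.01 to 0.67 and 0.60. On CPM the median of the 6 genes, 0.65, was at percentile 89.8, with 1 gene at least 2-fold higher in skin and 5 within 2-fold.

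Core Treg genes were mostly higher in skin. Of 19 with at least 20 CPM, 10 were at least 2-fold higher in skin and 3 in lung, with a median log2 ratio of 1.40 (percentile 100). Ikzf2, the gene of the transcription factor Helios, stood at 1629.8 against 570.2 CPM, and the inhibitory and costimulatory receptor genes Ctla4 at 1047 against 300.0 CPM, Icos at 1161 against 259 CPM and Tigit at 64.1 against 4.05 CPM. On the lung side were Gpr83 (15.4-fold, 11.8 to 20.5), Lrrc32, which encodes the TGF-beta docking receptor GARP (5.24-fold, 4.76 to 5.79), and Izumo1r, the gene of folate receptor 4, at 152 against 607 CPM.

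Genes of central and lymphoid-homing Tregs were lower in skin. Of 15, 0 were at least 2-fold higher in skin and 12 in lung, and the median of −2.38 was at percentile 0. Beside Satb1, Ly6c1 and S1pr1, the lymph node homing receptor gene Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077) stood at 117 against 619.8 CPM, Klf2 at 539 against 2437 CPM, and the transcription factor genes Lef1 and Tcf7 at 43.4 against 281 CPM and 31.2 against 191 CPM. A Ccr7 UMI was found in 11.6% of skin and 55.7% of lung T cells (6.41% and 36.8% thinned), against 12.3% and 19.6% in non-T clusters (2.90% and 10.1% thinned). Median depths of the T and non-T cells were 2026 and 4572 UMIs in skin, and 2335 and 2461 in lung. Il7r, Itgb7 and Il6ra were within 2-fold.

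Tissue and effector Treg genes stood on the skin side. Of 19, 17 were at least 2-fold higher in skin and 0 in lung, with a median of 2.13 (percentile 100). Itgae, which encodes the CD103 integrin chain that binds E-cadherin, was 32.0-fold (27.9 to 36.8) higher, Cd44 13.0-fold (11.9 to 14.2) and the nuclear receptor gene Rora 7.47-fold (7.06 to 7.91). Klrg1, a marker of terminally differentiated Tregs, stood at 236 against 30.1 CPM. A Cxcr6 UMI was found in 57.7% of skin and 0.499% of lung T cells (40.6% and 0.220% thinned), and in 31.9% and 0.321% of non-T cells (10.9% and 0% thinned).

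The type 2 associated genes had a median log2 ratio of 3.13 (percentile 100). As plain CPM ratios without the added 5, and with Il13 at its bound, their median was 3.93. Of 12, 10 were at least 2-fold higher in skin and 0 in lung. They included Gata3, the transcription factor gene of type 2 immunity, at 656 against 146 CPM, Il1rl1, the gene of the interleukin 33 receptor ST2, at 18.8-fold (15.9 to 22.2) higher, Ccr8 at 97.8 against 5.33 CPM and Il4 at 47.3 against 0.381 CPM. An Areg UMI was found in 68.8% of skin and 5.81% of lung T cells (51.7% and 2.90% thinned), and in 48.6% and 4.49% of non-T cells (21.7% and 1.49% thinned). Il13 UMIs were found in 19.9% of skin T cells (11.9% thinned) and 0 of 7811 lung T cells, and in 11.6% (3.62% thinned) of skin non-T cells. Il10 UMIs were found in 30.05% and 1.09% of T cells (18.8% and 0.647% thinned). The raw Il10 share of the deeper skin non-T cells was as high, at 31.9%, and 10.1% once thinned.

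All 5 measured repair and growth factor genes were at least 2-fold higher in skin, with a median of 3.53 (percentile 100). Beside Areg and Il1rl1, which the type 2 list also holds, these were Penk, which encodes the opioid peptide precursor proenkephalin (22.5-fold, 19.1 to 26.8), the protease gene Furin, also on the TGF-beta list, at 119 against 24.2 CPM and Notch1 at 51.9 against 16.8 CPM. Suppressive molecules, of which Il10, Ctla4, Tigit, Gzmb, Tgfb1, Pdcd1 and Lag3 are also on other lists, had a median of 2.29 (percentile 100), with 11 of 13 genes at least 2-fold higher in skin and 0 in lung. The granzyme gene Gzmb was 27.3-fold (23.1 to 32.4) higher and Fgl2, a secreted fibrinogen-like protein gene, 28.6-fold (24.8 to 33.2), while Lag3 and Nt5e stood at 23.2 against 16.1 CPM and 97.2 against 64.7 CPM.

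Genes of TGF-beta activation and response stood on both sides. Of 11, 6 were at least 2-fold higher in skin and 1, Lrrc32, in lung, with a median of 1.22 (percentile 99.99). Itgb8 and Itgav, whose integrin releases active TGF-beta, were 11.1-fold (9.30 to 13.4) and 6.11-fold (5.56 to 6.72) higher in skin. In the 326 skin and 271 lung cells with a Foxp3 UMI, the list median was 0.54 and lay inside the random range at percentile 82.5.

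Homing and adhesion receptors differed by member. Of 14 chemokine receptors, 9 were at least 2-fold higher in skin and 3 in lung (median 1.60, percentile 100). Beside Cxcr6, Ccr10 and Ccr8, skin was higher in Ccr6 (97.8 against 4.86 CPM) and Gpr55 (96.5 against 1.91 CPM), and lung in Ccr7, S1pr1 and Cxcr3, the receptor gene for interferon-induced chemokines (15.1 against 38.7 CPM). Against lung cluster 3 alone, a set of 1250 cells led by S100a4, Ccr2 and Ccl5 and chosen after seeing the data, this list had a median of −0.11, and in cells low in early response genes it lay just inside the random range at 0.87 (percentile 97.4). Of 14 integrin and adhesion genes, 6 were at least 2-fold higher in skin and 4 in lung (median 0.91, percentile 99.94), with Itgae and Cd44 on the skin side, and Ly6c1, Itga4 (15.1 against 83.1 CPM) and Itga6 (15.6 against 82.2 CPM) among those on the lung side. Against lung cluster 3 alone this list lay inside the random range at 0.20 (percentile 63.5).

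Receptor signalling genes were higher in skin together with early response genes. Of 16 genes induced by T cell receptor signalling, 13 were at least 2-fold higher in skin and 0 in lung (median 1.91, percentile 100). Nr4a1 stood at 1504 against 152 CPM, Nr4a3 at 222 against 17.1 CPM, Irf4 at 72.3 against 6.43 CPM and Cd69, an early activation and tissue retention receptor gene, at 836 against 165 CPM. For TNF receptor and costimulation genes the median was 1.39 (percentile 100), with 10 of 16 at least 2-fold higher in skin and 0 in lung, among them Tnfrsf9 at 249 against 58.1 CPM and Cd40lg at 113 against 12.5 CPM. Dissociation and early response genes, which enzymatic digestion also induces, had a median of 1.63 (percentile 100). Of 19, 13 were at least 2-fold higher in skin, such as Fosb (329.6 against 38.8 CPM), Atf3 (62.0 against 2.72 CPM) and Dusp1 (3828 against 774 CPM), and 3 in lung, Jun (167 against 415 CPM), Rhob and Socs3. In the median skin T cell they took 2.22% of UMIs, against 0.711% in lung. Heat shock genes split, with Hspa5 at 568 against 173 CPM, Dnaja1 at 745 against 302 CPM, and Hspa1a and Hspa1b at 97.8 against 332 CPM and 9.44 against 61.6 CPM. These last are near-identical paralogs. The heat shock median of −0.03 was at percentile 4.23, and turned to 0.04 with a floor of 5 CPM and to −0.47 with median-of-ratios scaling. It lay below the random range under 5 of 21 alternatives, median-of-ratios scaling (percentile 1.56) among them, with 2 of 13 genes at least 2-fold higher in skin and 3 in lung.

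Interferon-stimulated genes were higher in lung. Of 15, 0 were at least 2-fold higher in skin and 6 in lung (median −0.81, percentile 0). Ifi27l2a stood at 645 against 2688 CPM, Usp18 at 2.31 against 29.8 CPM, Ifit1 at 5.40 against 29.0 CPM and Rtp4 at 8.93 against 46.2 CPM.

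Glycolysis genes stood on the skin side, and oxidative phosphorylation genes were close. Glycolysis and hypoxia genes had a median of 1.07 (percentile 99.99), with 9 of 18 at least 2-fold higher in skin and 0 in lung, among them the glycolytic enzyme genes Aldoa (1173 against 259 CPM) and Tpi1 (217 against 46.4 CPM). Of 10 lipid and cholesterol genes, 5 were at least 2-fold higher in skin and 0 in lung (median 0.90, percentile 99.6), a list that fell inside the random range under 5 of 21 alternatives, at 0.57 (percentile 88.8) in cells with a Foxp3 UMI for example. Dgat2 and Fabp5 stood at 31.8 against 12.4 CPM and 72.3 against 25.2 CPM, and Apoe, at 128 against 7.43 CPM, reached 10901 CPM in skin non-T clusters. All 14 oxidative phosphorylation genes were within 2-fold (median 0.42, percentile 69.6). Of 15 proliferation genes, 13 were within 2-fold, with Mki67 at 22.6 against 8.43 CPM and Ube2c at 8.72 against 25.0 CPM. Their median was 0.36 (percentile 51.4) and turned to −0.03 under median-of-ratios scaling, while in cells low in early response genes, chosen after seeing the data, it lay above the random range at 1.27 (percentile 100).

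**Figure D2:**
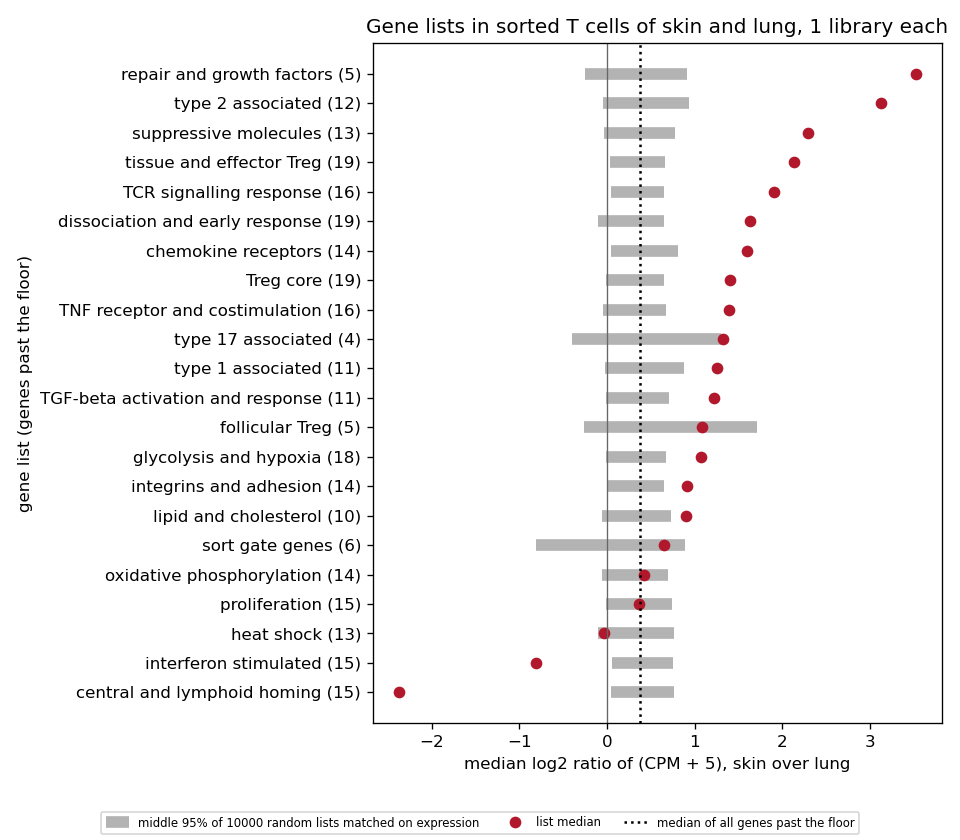
Median log2 ratio of (CPM + 5), skin over lung, of the 22 gene lists of T cell programmes (red points, number of genes past the floor in brackets) with the middle 95% of 10000 random lists matched on expression (grey bars) and the median of all genes past the floor (dotted line). Above the grey bars lie 15 lists, 2 lie below and 5 inside.

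Genes of other helper programmes were also compared. Of 11 type 1 associated genes, 6 were at least 2-fold higher in skin and 1, Cxcr3, in lung (median 1.26, percentile 99.95), and against lung cluster 3 alone the list lay inside the random range at 0.33 (percentile 77.6). The interleukin 18 receptor genes Il18r1 and Il18rap stood at 116 against 14.1 CPM and 30.3 against 1.38 CPM, and Nkg7 at 174 against 33.9 CPM. Of 4 type 17 associated genes, 2 were at least 2-fold higher in skin, Ccr6 and the aryl hydrocarbon receptor gene Ahr (70.5 against 18.7 CPM). The type 17 median of 1.32 was at percentile 97.7, just past the limit, and lay inside the random range under 7 of 21 alternatives. Of 5 follicular Treg genes, 3 were at least 2-fold higher in skin, such as Tox (281 against 130.5 CPM) and Bcl6 (21.5 against 3.76 CPM), with a median of 1.08 (percentile 85.6) that turned to −0.94 under median-of-ratios scaling. That put the list below the random range (percentile 0.95), with 3 genes past the floor, 0 at least 2-fold higher in skin and 1 in lung. A floor of 50 CPM also put it below that range (−0.63, percentile 0.93). Of 7 conventional CD4 T cell genes, 5 were at least 2-fold higher in skin, among them Il2 (63.5 against 6.81 CPM), Tnf (45.0 against 8.29 CPM) and Il4, and Ccr7 was higher in lung (median 1.99, percentile 99.99). Cd4, Ccr7, Bhlhe40, Cd40lg and Il4 of this list are also on other lists. All 5 measured ILC2 genes were at least 2-fold higher in skin (median 4.02, percentile 100). As plain CPM ratios without the added 5, and with Il13 at its bound, their median was 8.40. Of the 5 genes, Il13, Gata3 and Il1rl1 are shared with the type 2 list, and the others are Calca and Hlf (80.2 against 0.238 CPM). For CD8 T cell genes the median was 0.38 (percentile 42.2), with Ccl5 at 136 against 103 CPM and 1 of 3 genes, Nkg7, at least 2-fold higher in skin.

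Markers of other cell types appeared at low levels in the T cell pools. All 5 fibroblast genes were at least 2-fold higher in skin (median 2.81, percentile 99.5), with Dcn at 53.4 against 0.857 CPM beside 11039 CPM in skin non-T clusters. All 4 dendritic cell genes were higher in skin (median 2.47, percentile 99.77), with Cd74 at 362 against 33.8 CPM beside 6030.4 CPM in skin non-T clusters. Epcam, which is on this list and the epithelial one, stood at 63.5 against 4.81 CPM, against 27.9 CPM in skin non-T clusters. Airway and alveolar genes, Sftpc, Scgb1a1, Sftpa1 and Epcam, had a median of −3.65 (percentile 0). As plain CPM ratios without the added 5, and with the 3 genes at 0 in skin at their bound, it was −8.00. Of macrophage genes, Lyz2 stood at 16.1 against 38.2 CPM, Plac8 at 0.864 against 28.8 CPM and Ctss at 259 against 184 CPM (median −1.04, percentile 1.54). A single gene was measured for keratinocytes, Sfn at 38.8 against 14.5 CPM, for endothelium, Pecam1 at 38.9 against 98.0 CPM, and for plasma cells, Xbp1 at 98.8 against 42.7 CPM. No gene of the melanocyte, neutrophil, mast cell, B cell, gamma-delta T cell, NK cell or erythroid and platelet lists reached 20 CPM in either pool among shared identifiers, which cover 6 of 8 B cell genes and 2 of 7 gamma-delta T cell genes. Among genes that the lung annotation alone lists, the immunoglobulin genes Ighm, Igkc and Igha stood at 499, 137 and 51.0 CPM in the lung pool. Igha and Igkc were far higher in the proliferating lung cluster 9, at 853 and 2015 CPM against 5.21 and 38.6 in the other lung cells. The source of the 3 transcripts was not tested further.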

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

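The tests of the gene lists and of the Foxp3 reporter were chosen only after the results were seen; those of Sftpc and of the Treg genes beside Foxp3 were written before, the reading of the latter by library, against non-T clusters and with conventional genes came after, and the Sftpc pattern was narrowed from surfactant and club cell genes together after its test was run.

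Part of the data stayed outside the comparison. Clusters of other cell types held 138 skin cells (2.27%), led by fibroblast genes such as Dcn and Col1a2, and 312 lung cells (3.84%), led by endothelial genes such as Cldn5, by Scgb1a1 and by Sftpc. Genes listed only in the skin annotation took 0.330% of skin T cell UMIs, led by Gm8730 at 818 CPM. Those listed only in the lung annotation took 0.613% of lung T cell UMIs, led by the T cell receptor constant genes Trbc2 (2238 CPM), Trbc1 (1022 CPM) and Trac (746 CPM) and by the immunoglobulin gene Ighm (499 CPM), so that these were not compared.

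The type 2, effector and central lists stood apart between skin and lung, with medians of 3.13, 2.13 and −2.38. If the lung pool differed because it holds mostly central cells, lung cluster 3 alone should bring the lists into the random range, and it left them at percentiles 100, 100 and 0 with medians of 2.61, 0.95 and −1.36, so this is argued against as the whole cause and stays open as a cause of part of the effector and central differences. The same step was taken for an early response to digestion. Cells low in early response genes, 399 of 5941 in skin and 6477 of 7811 in lung, gave medians of 2.34, 1.96 and −2.03. These lay at percentiles 100, 100 and 0. In these cells the early response list fell from 1.63 to 0.56 (percentile 94.3), so its difference shrank but was not removed. The few skin cells kept also differed otherwise, since the proliferation list rose from 0.36 to 1.27. This argues against a response to digestion only as the whole cause, as far as these genes track it, and leaves part open. Of the genes at least 4-fold apart, 3.52% lie on X or Y, against 3.14% of all tested genes, so few of them are genes of the sex chromosomes. This count covers all genes far apart and not the 3 lists. It cannot speak to effects of sex on genes of other chromosomes. What also stays open is tissue itself, as the biological explanation that was not tested, and mouse strain, sex and library, which differ with tissue and cannot be told apart from it.

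Sftpc stood at 193 CPM in lung T cells, and 3141 of them (40.2%) had a UMI, although the sort for CD45, CD3 and CD4 should remove the alveolar cells that make it. Free RNA in the lung suspension is a candidate source: thinned to 1 depth, the share with a Sftpc UMI ran from 16.8% to 21.99% between lung T cell clusters of at least 200 cells, a ratio of 1.31, with a median of 1 UMI in positive cells. Doublets with epithelial cells are argued against as the source in the typical positive cell. That median is 0.0622% of the 1608 Sftpc UMIs of the median cell in the epithelium-like cluster. Cells with the highest doublet scores and the non-T clusters had been left out before, so doublets among those are not covered. Sftpc, Sftpa1 and Sftpb stood in T cells at 0.0756%, 0.0736% and 0.0826% of their levels in that cluster, close to 1 ratio. Scgb1a1, at 19.2%, was higher in lung cluster 10, which it leads, and no biological explanation was tested.

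Foxp3 UMIs were found in few sorted cells, 5.49% in skin and 3.47% in lung. That most sorted cells are not Tregs was set against Il2ra, Ctla4, Ikzf2, Tnfrsf18 and Tnfrsf4, whose summed CPM in T cells without a Foxp3 UMI was 0.974 (0.946 to 1.002) of that in cells with one in skin and 0.923 (0.879 to 0.969) in lung, where at least 0.8 had been set in advance as the bound for excluding it. In skin, Foxp3 stood at 2.79 CPM (0.338 to 10.1) in non-T clusters, below the 24.6 CPM of T cells. The intervals of the raw share with a Foxp3 UMI overlapped, at 1.45% (0.176 to 5.14) of 138 non-T cells against 5.49% (4.92 to 6.10). Foxp3 UMIs placed without regard to cell type would also give a ratio near 1. The bound therefore cannot decide the question in skin, where the explanation stays open. The 5 genes reached 18.7% of their T cell level in skin non-T clusters. A UMI of any of them was found in 99.7% of skin T cells and 92.0% of the deeper skin non-T cells. That share hardly separates T from non-T cells in skin. Il2, Cd40lg, Il4 and Tnf are conventional CD4 T cell genes that stood higher in skin than in lung. In skin they were no higher without a Foxp3 UMI (ratio 1.003, 0.880 to 1.147), which a split unrelated to cell type would also give. In lung the bound was wrong as well. Foxp3 in non-T clusters there, 6.24 CPM (2.51 to 12.9), overlaps the 13.3 CPM (11.8 to 14.9) of T cells. Free RNA may have placed the UMIs, so the lung cells with one need not be a Treg reference. The lung ratio of conventional genes, 0.674 (0.479 to 0.978), rests on the same split and cannot decide the question. In lung non-T clusters the 5 genes reached 13.2% of their T cell level. A UMI of any of them was found in 92.3% of lung T and 35.9% of lung non-T cells. Those values set T cells against other cell types, not against conventional CD4 T cells, so the explanation stays open in lung too. Whether the reporter inserted at Foxp3 moves reads off the gene cannot be told apart from a low level by the 13.3 CPM in lung, since no library without a reporter was used here.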

How the results depend on the processing

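Lung cluster 3 alone, cells low in early response genes, cells with a Cd3e UMI and leaving out proliferating clusters, X and Y genes, or overlapping and non-T genes were alternatives chosen only after the results were seen; the other 15 of 21 were planned. The type 2, effector and central lists stayed outside the random range on the same side under all 21, with medians of 2.12 to 3.62, 0.95 to 2.40 and −2.87 to −1.36. Of the 30 genes farthest apart, 0 of 624 alternative values reversed. The skin count of 212 genes became 139 with median-of-ratios scaling (139 shared), 94 with 20 CPM added in place of 5 (94 shared) and 135 with lung cluster 3 alone (123 shared). The lung count of 72 became 23 with 20 CPM added (23 shared) and 136 without mitochondrial and ribosomal protein genes in the total (72 shared). Adding more CPM shrinks every ratio by construction, and the other causes were not tested. The TGF-beta list fell inside the random range in cells with a Foxp3 UMI (0.54, percentile 82.5) and the early response list in cells low in it (0.56, percentile 94.3), which that selection favours. The chemokine receptor list turned to −0.11 (percentile 4.82) with lung cluster 3 alone, and the cause was not tested. Beside this value, 15 alternative values of the 17 other lists moved into the random range, 7 of them for the type 17 list, and 8 moved out of it. The Foxp3 share became 2.37% in skin and 1.47% in lung at 1000 UMIs per cell, where fewer UMIs per cell lower it by construction, and 2.90% in the shallower second lung matrix. The first lung matrix alone is the comparison itself. Clusters numbered 7 to 15 at resolutions 0.4 and 1.2, against 11 in skin and 12 in lung. Depth limits a gene at 0 to 0.216 CPM in skin and 0.143 CPM in lung. No paired analysis was possible because each tissue has 1 sample.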

Other observations

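The shared-programme test was chosen only after the result was seen, and the clusters were built from the same genes, so their levels are descriptions. Within the lung T cells, cluster 3 (1250 cells) stood apart from the rest. Relative to all lung T cells its mean log2 level was higher by 1.06 in effector, 1.03 in type 1 and 0.91 in suppressive genes, and lower in central genes (−0.92). It held Il10 at 32.7 CPM and Areg at 70.7 CPM, with 0 UMIs of Il13. Against this cluster the skin pool was 9.92-fold (8.41 to 11.8) higher in Il10 and 18.2-fold (16.3 to 20.4) higher in Areg. Gata3 stood at 656 CPM in skin against 200.7 CPM in the cluster, and Il1rl1 at 138 against 24.6 CPM. Ccr2 and Ccr4, receptor genes of tissue-homing T cells, were close, at 224 against 242 CPM and 53.6 against 64.0 CPM, and Cxcr3 was higher in the cluster, at 15.1 against 133 CPM. Lung cluster 6 (403 cells), named effector Treg-like by its markers, stood −0.29 from all lung T cells in effector genes. That is above lung clusters 1, 2, 4, 5 and 7, at −1.40 to −0.88, and below cluster 3. Cluster 6 was nearer to skin in Areg, one of its leading genes, at 242 CPM against 1285 CPM in the skin pool. The same held for Penk, at 61.9 against 157 CPM. The proliferating lung cluster 9 (138 cells), which is part of the T cell pool, was led by Igha at 853 CPM and also held Igkc at 2015 CPM and Jchain at 312 CPM, all plasma cell genes.

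Within the skin T cells, cluster 5 (739 cells), the central Treg-like one, stood 0.77 above the skin mean in central genes and 0.72 in follicular Treg genes. Il13 was found in every skin T cell cluster, at 44.5 to 409 CPM, and in none of lung. Skin non-T clusters held it at 30.7 CPM, so the lowest of these levels is near background.

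A hypothesis is that part of the skin programme is shared with lung cluster 3. Across 5785 genes, skin over a random part of the other lung T cells and lung cluster 3 over the remaining part correlated at a Spearman rho of 0.407 (Pearson r 0.485). Of 272 genes at least 4-fold higher in skin than in the first part, 110 (40.4%) were at least 2-fold higher in cluster 3 than in the other part and 0 were lower, against 5.07% of 5563 genes past the floor that were higher. Of 74 genes at least 4-fold higher in that lung part, 25 (33.8%) were at least 2-fold lower in cluster 3 and 2 were higher, against 1.02% of genes past the floor that were lower. Cells and not libraries were split, so part of the correlation may come from the shared lung library, and genes are not independent replicates.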
